A study of Drosophila melanogaster with 42 samples.

How the data were processed

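The deposited data are 42 tables, 1 per sequencing library, from an assay of candidate regulatory regions in Drosophila embryos. Per the labels' protocols, embryos were collected for 2 to 2.5 h at 25 °C and aged for 9 to 10 h at 18 °C. Cells were stained for CD2 and sorted, and crude genomic DNA was prepared. Stored extracts were pooled by sample type, divided into 5 PCR templates and amplified by nested PCR, and 5 µg of product was sonicated, ligated to adapters and amplified for 10 cycles. The cell numbers in the labels run from 16163 to 200000 per library. Per the submitters' processing notes, CASAVA 1.8 was used and the genome build was dm3. The mapper's version is not given in the sources used here.

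The deposited tables list each region with its dm3 coordinates, its read columns and its GC content. Per the file headers, 1 column is the read count at the start of a region, 1 the count at its end, and 1 a weight, which was checked to be the sum of both in all 20655 lines. The deposited total per region behaves as an expected count. It is the weight plus other reads, and 2 to 87 regions per library hold fractions. These were taken as reads divided between overlapping or duplicated regions, which was not tested. Of the regions named by the rule, ChIPCRM2497, ChIPCRM2613, ChIPCRM4832, ChIPCRM5404, ChIPCRM5819 and CG15319_down_8 overlap another. GC content is deposited as a fraction of the region, and its product with the region length was whole in all lines, so coordinates are inclusive. The definition of a further deposited column of whole numbers, on covered positions, is not given in the sources used here, and it was not used. In 11 tables, 3 regions were listed under 2 names each and were merged. No values were normalised by the authors as far as the tables show.

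The total per region was rounded to whole numbers and analysed as counts. Libraries held 15601850 to 30671354 reads, so 3 reads, taken as the floor for a count of 0, correspond to 0.0978 to 0.192 CPM. CPM, counts per 1e6, scales the reads of a region to those in all regions of its library. These are PCR reads without molecular identifiers and not independent molecules, so intervals and floors cover counting error only. Where a group had 0 reads, a bound was computed against 3 reads over the group. Where it had 1 read, the ratio was given with an exact 95% interval.

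The main test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM scaling, filterByExpr, quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05 per comparison. Each of the 6 GFP+ populations was compared with the input that the series design assigns to it. For each driver, a fit over 4 groups tested whether enrichment differed between CD2+ and CD2- cells, and inputs were compared with each other as background. A single GFP+ library was assumed to vary like its inputs. Standard errors are the absolute log2 change over the square root of F. The estimated biological variation was 127% to 179%. The design, tests, gene lists, rule for named regions and first set of alternatives were chosen before the data were examined.

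TMM centres the bulk of the regions, while GFP+ cells hold a few very abundant ones. Scaling by total reads moved log2 changes, by the median over regions of the move, by -1.61 in twi CD2+, -1.30 in twi CD2-, 0.04 in mef2 CD2+, -1.57 in mef2 CD2-, -0.53 in duf CD2+ and -2.08 in duf CD2- cells. It moved the differences of enrichment by -0.39, 1.89 and 1.24 for twi, mef2 and duf, and the input comparisons by -0.18, -0.10 and -0.38. Log2 changes are given on the TMM scale, on which the median region was not at 0 in all tests (-2.29 in mef2 CD2+ and -0.72 in duf CD2+ cells, -1.45 and -0.80 in the mef2 and duf differences). CPM values, bounds and ratios of reads are on the scale of total reads.

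Named regions were those past the threshold whose CPM in every GFP+ library lay above, or below, every input, up to 15 higher and 5 lower per comparison, up to 5 per direction in other tests, and any region named for a driver gene. Gene symbols came from region identifiers. Of 107 regions named for a gene, 105 matched 1 symbol in a RefSeq gene table (47 genes), which is of a later assembly and was used for names only. The other regions, 288 named ChIPCRM, 49 DHS_FC, 38 CBP and 9 DHS_FCM, carry no gene name, and their place in genes was not analysed here. Gene lists for somatic muscle and founder cells, cardiac and visceral mesoderm, blood and fat body, nervous system and glia, epidermis and segmentation, and trachea, gut and gonad were tested with camera at a preset correlation of 0.01 where at least 5 regions were tested.

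No pair of libraries within a group had identical values or agreed within sampling noise. Replicate numbers are shared between GFP+ cells and inputs in the labels. Deviations from the group means of same-numbered libraries correlated at 0.17 to 0.31 in twi CD2+, 0.18 to 0.25 in twi CD2-, 0.18 to 0.39 in duf CD2- cells and 0.47 to 0.69 between the twi inputs, so the numbers were taken to pair the libraries there. That pairing comes from the data and not from a statement in the labels. Correlations between differently numbered libraries are not given for reference.

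Alternatives were DESeq2 1.42.0 with its own size factors, total-read scaling, no filter, a mean count of at least 100, leaving out each library, the replicate number or sequencing lane as a block, all CD2- inputs as control, and the spread estimated from all 4 groups of a driver. Counting end reads only or other reads only, the split of duf replicates into 1 to 3 and 4 to 6, the small inputs as control for duf CD2- GFP+ cells, and a replicate block shared by CD2+ and CD2- cells were added after the data were seen. Both tools were tested on simulated counts drawn from the real means and TMM-scaled library sizes, with the spread of each region as estimated by edgeR. Tables, permutation tests and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.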

Results

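Candidate regulatory regions of about 1 kb were assayed in whole Drosophila melanogaster embryos by sorting cells on reporter expression and counting the regions that the sorted cells carried. In this design each fly of a transgenic pool carries a candidate region in front of a GFP reporter. The pool was crossed to flies that express the rat surface protein CD2 under a driver named twi, mef2 or duf. The drivers carry the names of twist, a transcription factor gene of the early mesoderm, Mef2, a transcription factor gene of muscle differentiation, and dumbfounded (kirre), a cell adhesion gene of muscle founder cells. Cells were separated into CD2+ and CD2- populations, and GFP+ subsets of these were collected beside inputs not selected on GFP. The inserted regions were then amplified from genomic DNA and sequenced, so that a region active in a population should take a larger share of the reads in its GFP+ cells than in its input.

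The 42 libraries formed 12 groups. For twi, CD2+ GFP+ cells, CD2+ input, CD2- GFP+ cells and CD2- input had 3 libraries each. For mef2, CD2+ GFP+ cells had 1 library with 5 CD2- inputs of 20048 to 32326 cells beside it, called small inputs here, and CD2- GFP+ cells and CD2- input had 3 each. For duf, CD2+ GFP+ cells had 1 library with 5 small CD2- inputs of 39668 cells, and CD2- GFP+ cells and CD2- input had 6 each. The titles of the small duf inputs give CD2 without a sign, and they were taken as CD2- here. The labels call both single GFP+ libraries pooled. Nothing in the labels says that replicates came from separate crosses, and p-values then measure only the spread between these libraries, which may be technical.

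Each library held between 15601850 and 30671354 reads in 491 regions of 900 to 1101 bp, and 26 regions had no read in any library. The number of regions seen differed between duf libraries and those of the other drivers, also among inputs not selected on GFP. The twi inputs held 155 to 188 regions with at least 100 reads and the 200000-cell mef2 inputs 157 to 172. The labels give lanes for duf libraries only, so driver, batch and fly pool cannot be told apart here. Between 93 and 193 regions had at least 100 reads in a twi or mef2 library, against 368 to 409 in the 200000-cell duf inputs, 313 to 337 in the small duf inputs and 273 to 346 in the duf CD2- GFP+ libraries. GFP+ libraries with replicates came mostly from fewer cells than their inputs, 36206 to 55331 against 200000 in duf CD2-, 94473 to 138635 against 200000 in mef2 CD2- and 63849 to 111875 against 100000 to 200000 in twi cells, so cell number differed along with GFP. GFP+ cells were dominated by few regions. The 10 most abundant regions of a library took 69.2% ± 6.18 of the reads (SD, n = 3) in twi CD2+ GFP+ cells and 31.2% ± 0.328 (n = 3) in their input, and 57.9% ± 3.24 (n = 6) in duf CD2- GFP+ cells against 15.4% ± 1.13 (n = 6).

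**Figure D1:**
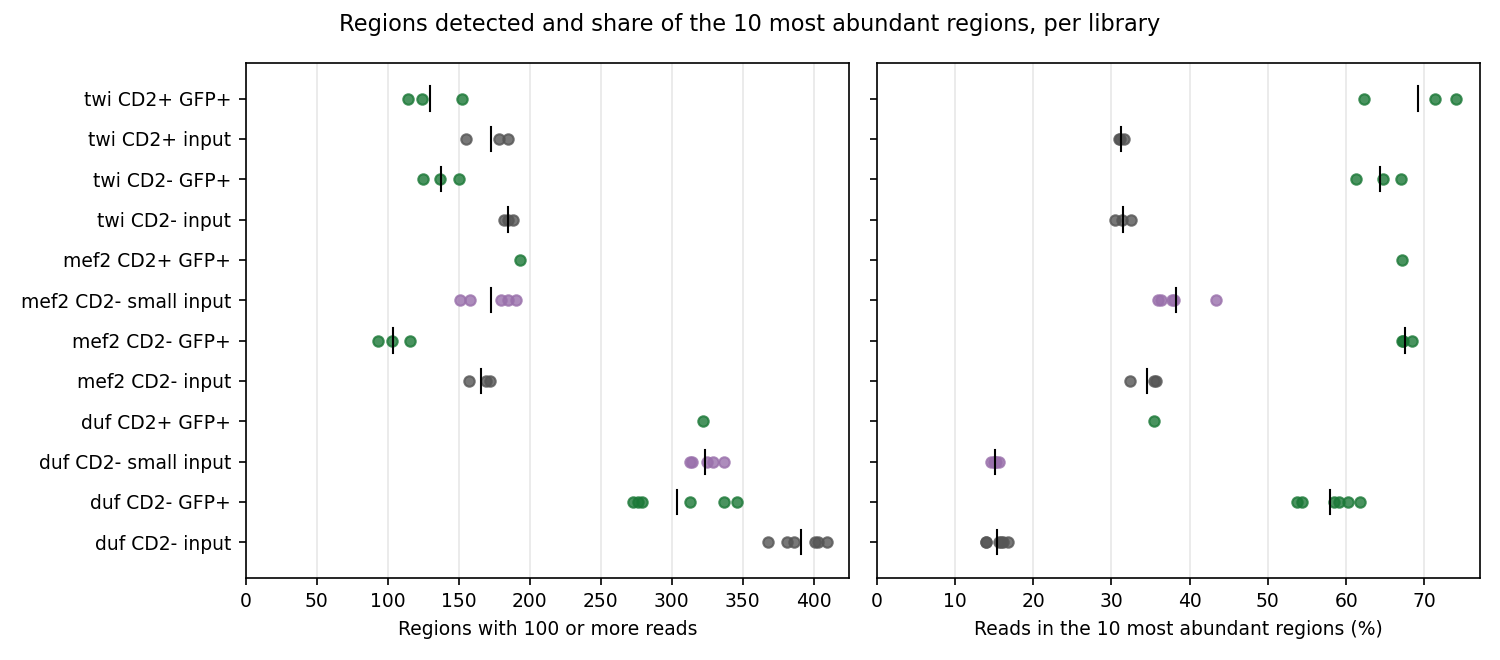
Regions with at least 100 reads (left) and percent of reads in the 10 most abundant regions (right), 1 point per library with a bar at the group mean where a group has more than 1 library. Inputs not selected on GFP (grey, and purple for small cell numbers) lie at or below 43.3% on the right, and GFP+ libraries (green) lie at 53.7% or more, except for the duf CD2+ library at 35.5%.

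The first comparison asked which regions were active in twi CD2+ cells. CG7759_33 (dm3 2R 7287136 to 7288168), whose identifier names the gene Smyd4-3 of the SET and MYND domain family, rose from 8565 ± 3022 to 159493 ± 36588 CPM (reads of the region scaled to the library's total, mean ± SD, n = 3 each). ChIPCRM3152 (3R 21835656 to 21836646) was the most abundant, at 203210 ± 32409 CPM against 41488 ± 1542 in the input, and ChIPCRM2907 (3R 17989695 to 17990673) had 121899 ± 15813 CPM against 21932 ± 6235. ChIPCRM2300 (3R 10415270 to 10416230) went from 33.2 ± 49.5 CPM, with inputs from 1.95 to 90.3, to 9603 ± 2716 CPM. ChIPCRM2299, 1842 bp away, went from 5963 ± 2605 to 36150 ± 4059. After TMM scaling, log2 changes were 9.72 ± 1.82 (SE) for ChIPCRM2300, 5.86 ± 0.44 for CG7759_33, 4.11 ± 0.37 for ChIPCRM2907 and 3.92 ± 0.26 for ChIPCRM3152, with adjusted p of 0.0121, 5.25e-05, 0.000153 and 3.85e-05 by edgeR's quasi-likelihood test. ChIPCRM2497, ChIPCRM2754, ChIPCRM2299, ChIPCRM2898 and ChIPCRM2256 rose by 2.82 to 5.31 on the log2 scale, and ChIPCRM2847, the only call whose groups overlapped, by 2.97. Of 195 regions tested by edgeR, 10 were higher and 0 lower, with 26 at an unadjusted p under 0.05, and DESeq2 called 13 higher, 8 of them among the 10, and 11 lower, with an adjusted p of 0.0671 for ChIPCRM2256. GFP+ values lay above all inputs for 13 regions and below them for 81, where chance separates 10% of regions in a comparison of 3 against 3. Separation was judged in CPM, on the scale of total reads, where a few abundant GFP+ regions lower the CPM of the others. The 81 therefore cannot be set against that share. Scaled by total reads, the split was 6 higher and 4 lower, and ChIPCRM2754, ChIPCRM2898 and ChIPCRM2256 had adjusted p of 0.0694 to 0.129. Without twi CD2+ GFP+ replicate 2 there were 5 calls, and ChIPCRM2300, ChIPCRM2754, ChIPCRM2898 and ChIPCRM2256 had adjusted p of 0.0574, 0.0574, 0.0574 and 0.0579. Without GFP+ replicate 1, 1 region was lower. The log2 change of ChIPCRM2300 ran from 8.18 to 12.6 over 13 alternatives.

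In twi CD2- cells, those without CD2 staining, the question was again which regions were active, and the same 3 regions as in twi CD2+ cells had the highest CPM. ChIPCRM3152 took 267761 ± 21169 CPM in GFP+ cells against 43442 ± 6208 in the input (n = 3 each), ChIPCRM2907 took 134824 ± 13215 against 12828 ± 1680, and CG7759_33 took 59813 ± 12679 against 8566 ± 4408. Their log2 changes were 3.92 ± 0.14, 4.70 ± 0.17 and 4.14 ± 0.41, with adjusted p of 1.46e-07, 1.46e-07 and 0.000363. CBP5467 (2R 16487993 to 16489070, log2 change 3.44) and ChIPCRM2898 (3R 17959709 to 17960651, 3.34) were also higher. ChIPCRM3147 (3R 21824689 to 21825693), near absent from the input at 1.16 ± 1.01 CPM with 1 library at 0, had 2722 to 33365 CPM in GFP+ cells and the largest log2 change of the calls, 15.14 ± 2.51. These 6 were the calls among 204 regions, each separated from its input in all libraries, against 0 lower, 28 regions at an unadjusted p under 0.05, and 17 higher and 9 lower by DESeq2. Total-read scaling gave 5 higher and 1 lower and an adjusted p of 0.0664 for CBP5467. Without twi CD2- GFP+ replicate 1, ChIPCRM3147 had an adjusted p of 0.0864 and CBP5467 of 0.0757, and without twi CD2- input replicate 3 ChIPCRM3147 had 0.064. By edgeR, ChIPCRM3147 also had log2 changes of 12.75 ± 3.28 in twi CD2+ cells (adjusted p 0.0609) and 14.39 ± 3.91 in mef2 CD2- cells (0.0611). Neither passed the threshold.

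Whether enrichment differed between twi CD2+ and CD2- cells was tested in a fit over the 4 groups. The regions with the smallest p were ChIPCRM2300, at a log2 difference of 13.79 ± 3.03, and ChIPCRM2754, at 5.23 ± 1.18, each with an adjusted p of 0.0707. CG7759_33 differed by 1.74 ± 0.60 (adjusted p 0.214), ChIPCRM3152 by 0.02 ± 0.28 (0.994) and ChIPCRM2907 by -0.57 ± 0.39 (0.875). ChIPCRM2300 and ChIPCRM2754 were singled out after their values were seen. Of 211 regions edgeR called 0 higher and 0 lower, with 22 at an unadjusted p under 0.05, and DESeq2 called 5 and 7. Without CD2+ GFP+ replicate 3, CD2- input replicate 1 or CD2- input replicate 3 there was 1 region higher, without CD2+ input replicate 2 there were 2, and without CD2+ input replicate 3 there was 1 higher and 1 lower. As background, CD2+ input against CD2- input gave 0 and 0 of 204 by edgeR, 3 at an unadjusted p under 0.05, and 3 and 2 by DESeq2.

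In the single mef2 CD2+ GFP+ library, CG7759_33 again stood out, at 120153 CPM against 1305 ± 1335 in the 5 small inputs. Its log2 change was 6.44 ± 1.34 (edgeR quasi-likelihood, adjusted p 0.0484), and it was the only call among 230 regions in this fit, with 0 lower and 16 at an unadjusted p under 0.05. DESeq2 called 1 higher, which was another region since CG7759_33 had an adjusted p of 0.0864 there, and 1 lower. The inputs were CD2- cells, so the comparison joins the CD2 and the GFP sort, and the single library was assumed to vary like the inputs. The call was lost without small input replicate 1 (0.0605) or replicate 5 (0.132), there were 2 higher without replicate 3, and 1 was lower without replicate 4. With the spread from all 4 mef2 groups there were 5 higher and 1 lower, with all CD2- inputs as control 4 and 6, and at a mean count of at least 100 there were 2 and 2. The library lay above every input for 30 regions and below for 28, against a chance share of 33.3% for 1 against 5.

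In mef2 CD2- cells the largest gain among called regions was that of ChIPCRM2078 (3R 7177448 to 7178448), from 7284 ± 1417 to 138345 ± 2224 CPM (n = 3 each), a log2 change of 5.81 ± 0.24 with an adjusted p of 3.57e-06. CG7759_33 rose from 6898 ± 2118 to 121436 ± 6468 CPM (5.71 ± 0.27, 4.97e-06), ChIPCRM3152 from 14502 ± 6253 to 115704 ± 12433 (4.59 ± 0.37, 0.000119) and ChIPCRM2907 from 20780 ± 6191 to 99141 ± 7614 (3.80 ± 0.29, 0.000116). ChIPCRM5284 (2L 2164492 to 2165474), ChIPCRM5819 (2L 9988389 to 9989430), ChIPCRM5556, CBP2861 (3L 317954 to 319048), ChIPCRM2299 and ChIPCRM2847 rose by 2.28 to 4.80. Other regions were lower in GFP+ cells. CBP7342 (3R 21307511 to 21308494) had 0 reads in the 3 GFP+ libraries against 3038 ± 1231 CPM, at least 56299-fold lower in CPM against a floor of 3 reads over the group, ChIPCRM2506 was at least 26278-fold and CBP4280 at least 509-fold lower. On the TMM scale these bounds are about 2.98 times smaller. They allow for counting error in the GFP+ libraries and not for the spread between inputs. Without input replicate 3 the bound for CBP7342 was 46185-fold. Without input replicate 2 it was 18507-fold for ChIPCRM2506 and 357-fold for CBP4280. ChIPCRM4832 had 31 reads in GFP+ cells against 231373, and ChIPCRM2983 had 1 read, a ratio of 66921 in CPM with an exact 95% counting interval of 12011 to 2643270. Its inputs ranged from 102 to 3238 CPM, and without input replicate 2 the ratio was 10659, outside that interval.

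The test gave 10 regions higher and 7 lower of 183 in mef2 CD2- cells, and DESeq2 called 30 higher and 25 lower. All 17 edgeR calls were among the 16 and 76 regions separated above and below the input, where chance separates 10% for 3 against 3. Separation was judged in CPM, where abundant GFP+ regions lower the others, so the 76 cannot be set against that share. Total-read scaling gave 7 higher and 17 lower, and ChIPCRM5556, ChIPCRM2299 and ChIPCRM2847 had adjusted p of 0.168 to 0.240. The lower calls lay close to the threshold. With the replicate number as a block there were 7 higher and 0 lower, and the named lower regions had an adjusted p of 0.156. Without a filter on low counts CBP7342, ChIPCRM4832, ChIPCRM2506, ChIPCRM2983 and CBP4280 had adjusted p of 0.0600 to 0.0880, and at a mean count of at least 100 the last 3 had 0.0573 to 0.0846. The lower calls fell to 0 without GFP+ replicate 3 or any 1 of the 3 inputs and to 3 without GFP+ replicate 2, and ChIPCRM2506, ChIPCRM2983 and CBP4280 were each lost without any 1 of the 6 libraries, at adjusted p of 0.0516 to 0.137. Without input replicate 1, 2 or 3, CBP7342 had adjusted p of 0.116, 0.136 and 0.122 and ChIPCRM4832 had 0.116, 0.123 and 0.122, and without GFP+ replicate 3 they had 0.0505 and 0.0574. ChIPCRM4832 had 0.0506 without GFP+ replicate 1. Among the higher regions, ChIPCRM5556 was lost without GFP+ replicate 2 or 3 or any 1 input (0.0702 to 0.144), ChIPCRM2847 without any 1 input (0.056 to 0.094), and ChIPCRM2299 without GFP+ replicate 3, input replicate 2 or input replicate 3 (0.0505, 0.0866 and 0.116).

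The mef2 difference test, in which the median region lay at -1.45, called 1 region. ChIPCRM1831 (3R 4512729 to 4513672) had a lower ratio of GFP+ cells to input in the single mef2 CD2+ GFP+ library than in the mef2 CD2- libraries. It was not called as enriched in mef2 CD2- cells (log2 change 0.88 ± 0.41, edgeR adjusted p 0.243). It had 903 CPM in the CD2+ GFP+ library against 40618 ± 9771 in its 5 small inputs, and 21856 ± 10718 CPM in CD2- GFP+ cells against 34019 ± 4997 in their input (n = 3 each). The log2 difference was -6.74 ± 1.27 with an adjusted p of 0.0162 by edgeR, with the single library assumed to vary like the other groups, so a difference between the cell populations is not shown. ChIPCRM2078, the leading region of CD2- cells, differed by -2.33 ± 0.98 (adjusted p 0.291) and CG7759_33 by 0.37 ± 1.39 (0.931). Of 231 regions, 0 were higher and 1 lower, with 37 at an unadjusted p under 0.05, and DESeq2 called 15 and 14. The call was lost with total-read scaling (log2 difference -4.85, adjusted p 0.0571), without a filter on low counts (0.0883), without small input replicate 3 (0.0766), CD2- GFP+ replicate 2 (0.0657) or 3 (0.097), or CD2- input replicate 1, 2 or 3 (0.0606, 0.0653 and 0.0624), and 2 regions were lower without small input replicate 1. As background, small inputs against the 200000-cell inputs gave 0 and 0 of 221 by edgeR, 49 at an unadjusted p under 0.05, and 27 and 17 by DESeq2.

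In the single duf CD2+ GFP+ library, ChIPCRM2889 (3R 17870003 to 17870903) had 37647 CPM against 2704 ± 1058 in the 5 small CD2- inputs. Its log2 change was 4.32 ± 0.63 (edgeR quasi-likelihood, adjusted p 0.0371), the only call among 425 regions in this fit. With the spread from all 4 duf groups 11 were higher, and with all CD2- inputs as control 10 were higher and 3 lower. CG7759_33 had a log2 change of 5.14 ± 1.57 that did not pass (adjusted p 0.305). There were 0 regions lower and 30 at an unadjusted p under 0.05, and DESeq2 called 9 higher and 68 lower. Total-read scaling gave 0 calls, and the call was lost without small input replicate 1, 2, 4 or 5, at adjusted p of 0.138, 0.128, 0.0508 and 0.0942. The library lay above every input for 52 regions and below for 105 in CPM, against a chance share of 33.3% for 1 against 5. The inputs were taken as CD2- cells, so the comparison joins the CD2 and the GFP sort. The single library was assumed to vary like the inputs, so the p-values rest on their spread alone. Mef2_29 (2R 5830342 to 5831294), named for a driver gene, had 111 CPM against 361 ± 605 (log2 change -1.14 ± 4.67, adjusted p 0.984).

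The duf CD2- cells, with 6 libraries on each side, gave the longest list. CBP4242 (3L 20394856 to 20395883) rose from 2897 ± 1976 to 172338 ± 18513 CPM, a log2 change of 7.97 ± 0.58 with an adjusted p of 4.36e-08. CG7759_33 rose from 971 ± 561 to 58085 ± 16221 CPM (7.94 ± 0.58, 4.43e-08), ChIPCRM2907 from 2129 ± 933 to 39354 ± 14006 (6.29 ± 0.43, 3.44e-08), and ChIPCRM5432 (2L 4363360 to 4364283) from 6137 ± 1485 to 64678 ± 16815 (5.49 ± 0.31, 3.48e-09). ChIPCRM2889, the region called in the single duf CD2+ library, rose from 5357 ± 2523 to 55226 ± 16508 CPM (5.41 ± 0.44). ChIPCRM5284 had the largest fitted change, 8.52 ± 1.45, from inputs that ranged from 3.11 to 1123 CPM. CBP4244, 2272 bp from CBP4242, and ChIPCRM5479, ChIPCRM1586, ChIPCRM5792, ChIPCRM5819, ChIPCRM5404, ChIPCRM2613, CBP2861 and ChIPCRM2299 rose by 4.09 to 6.09. Lower regions were ChIPCRM422 (2R 6386212 to 6387295, 7 reads against 39358), ChIPCRM2983 (51 against 61316), CG15319_down_8, a region named for the histone acetyltransferase gene nej (42 against 9432, with 30 to 3135 in single inputs), and ChIPCRM4243 (674 ± 329 against 7980 ± 1404 CPM, log2 change -1.54 ± 0.47). CG15319_down_8 overlaps CG15319_down_7 and CG15319_down_9, so reads in the shared parts may have been divided between them. Mef2_29 had 102 ± 168 CPM against 1035 ± 825 (-1.23 ± 1.54, adjusted p 0.932).

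Of 400 regions in duf CD2- cells, 47 were higher and 5 lower by edgeR, of which 16 and 4 were separated in all 12 libraries. Over all 400, 16 regions lay above and 89 below every input, where chance separates 0.216%. Separation was judged in CPM, on the scale of total reads, which moved log2 changes by -2.08 here. The few abundant regions of GFP+ cells lower the CPM of the others, so the 89 cannot be set against that share. DESeq2 called 58 and 6. Against the small inputs, whose 39668 cells are closer to the number of GFP+ cells, there were 25 higher and 1 lower of 387, with 22 and 1 of the calls among them. There ChIPCRM5284, CBP4244, ChIPCRM1586 and ChIPCRM4243 had smaller log2 changes, of 5.91, 3.87, 4.41 and -1.15, with adjusted p of 0.0757, 0.219, 0.127 and 0.744. ChIPCRM422 and CG15319_down_8 did not pass the filter. Total-read scaling gave 22 higher and 95 lower. With the replicate number as a block, which was taken to pair GFP+ and input libraries here, there were 42 higher and 2 lower. CG15319_down_8 and ChIPCRM4243 then had adjusted p of 0.123 and 0.0707. The inputs fell into replicates 1 to 3 and 4 to 6, and fits within these gave 43 higher and 5 lower, and 27 higher and 5 lower, with 39 and 26 of the 47 higher and 1 and 0 of the 5 lower regions among them. ChIPCRM5479, ChIPCRM422 and ChIPCRM2983 had adjusted p of 0.0518, 0.0651 and 0.076 in replicates 4 to 6, and ChIPCRM422 had 0.0507 in replicates 1 to 3. With the sequencing lane as a block, which only 5 libraries in lanes 1 and 8 allow, no region passed (0 higher and 0 lower of 411, 69 at an unadjusted p under 0.05), and the named higher regions had adjusted p from 0.0711 to 0.394. Their log2 changes were 4.09 to 12.04 there, against 4.09 to 8.52 over all 12 libraries. Without a filter on low counts CG15319_down_8 and ChIPCRM4243 had adjusted p of 0.0882 and 0.0576, CG15319_down_8 had 0.0722 at a mean count of at least 100, and ChIPCRM4243 had 0.0632 from end reads only. The lower count was 8 without GFP+ replicate 2, 3 without GFP+ replicate 3, input replicate 2 or input replicate 3, and 2 without input replicate 1, 5 or 6. ChIPCRM4243 was lost without GFP+ replicate 1, 3 or 5 or any 1 of the 6 inputs (0.051 to 0.106), and CG15319_down_8 without any 1 GFP+ replicate or input replicate 1, 3, 5 or 6 (0.0534 to 0.0947).

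**Figure D2:**
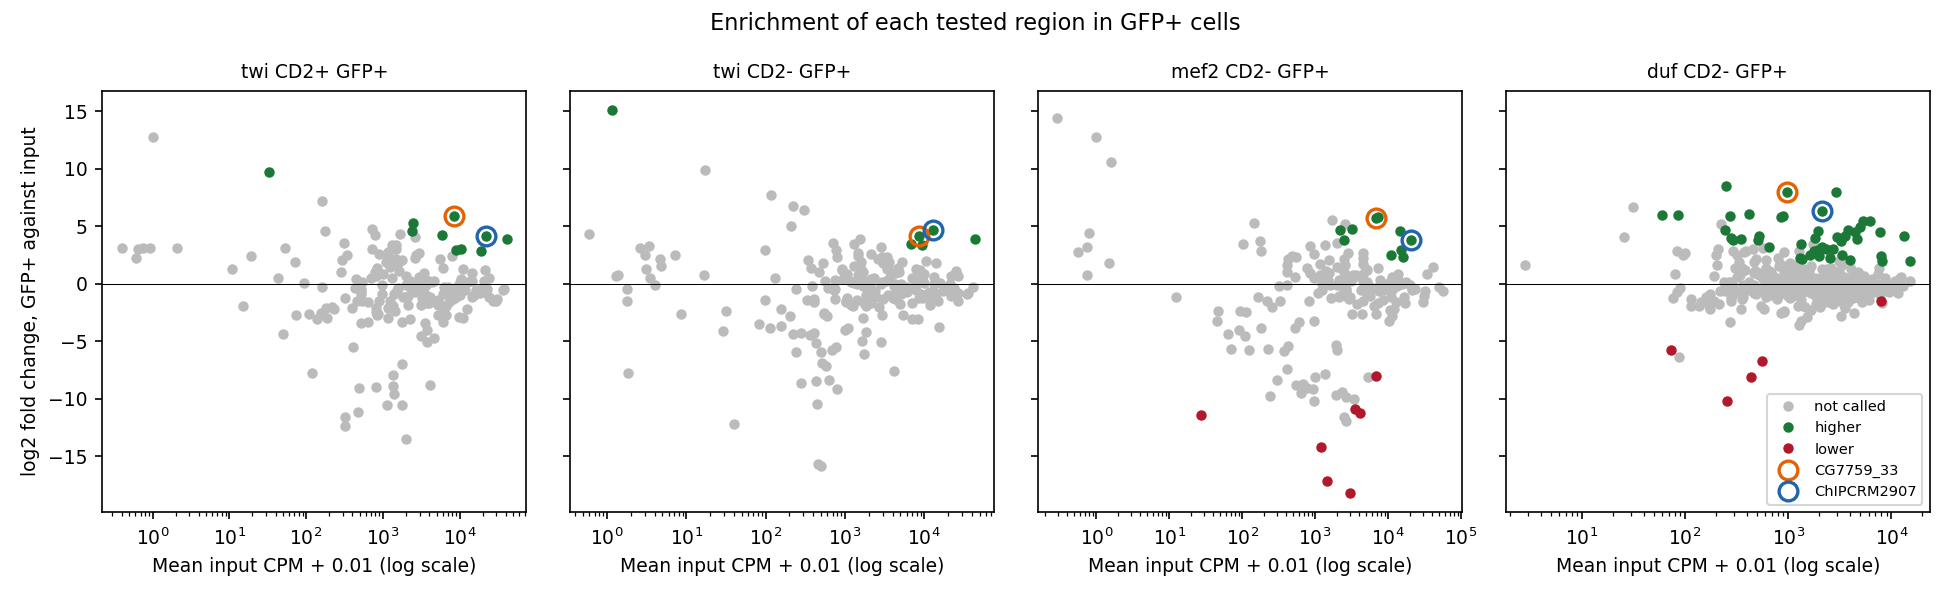
Log2 fold change of each tested region in GFP+ cells against its input, over the mean CPM of the input plus 0.01 on a log axis, for the 4 comparisons with replicates on both sides (green higher, red lower, grey not called). CG7759_33 and ChIPCRM2907, ringed, were called higher in each of the 4, with log2 changes from 3.80 to 7.94.

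The difference in enrichment between duf CD2+ and CD2- cells rests on a single CD2+ GFP+ library set against small CD2- inputs. A property of that library and a difference between the cell populations are therefore confounded. ChIPCRM2889, called in both, differed by -0.77 ± 0.93 (adjusted p 0.874), and CBP4242 by -2.22 ± 1.58 (0.747). Of 430 regions edgeR called 0 and 0, with 30 at an unadjusted p under 0.05, while DESeq2 called 1 higher and 82 lower. Mef2_29 differed by 0.36 ± 3.73 (adjusted p 0.994), and its estimate was -0.08 without CD2- input replicate 1. As background, small inputs against the 200000-cell inputs gave 0 and 0 of 412 by edgeR, 21 at an unadjusted p under 0.05, and 3 and 5 by DESeq2, with Mef2_29 at -1.11 ± 1.68 (0.959).

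The 6 comparisons share no library, so a region that recurs does so in separate libraries. Same-numbered twi CD2+ and CD2- inputs were taken as paired, so the twi comparisons are not independent of each other. CG7759_33 and ChIPCRM2907 were called higher in the 4 comparisons with replicates on both sides, and CG7759_33 also in the single mef2 CD2+ library, where the call was not stable. ChIPCRM2299, ChIPCRM3152 and ChIPCRM2898 were called in 3, while 8 regions were called in 2 and 41 in 1. ChIPCRM3152 was not among the regions tested in duf CD2- cells. Calls of mef2 CD2- and duf CD2- cells shared 7 regions where 1.19 would be shared by independent lists (hypergeometric p 5.13e-06, adjusted over 15 pairs 7.70e-05). Those of twi CD2+ and twi CD2- cells shared 4 against 0.313 (adjusted p 0.000299), and those of twi CD2+ and mef2 CD2- cells 5 against 0.610 (0.000299). The pairs twi CD2+ with duf CD2-, twi CD2- with mef2 CD2- and twi CD2- with duf CD2- shared 5, 3 and 4, with adjusted p of 0.00441, 0.00666 and 0.000751. No pair with mef2 CD2+ or duf CD2+ cells passed. These p-values take each region as an independent draw that is equally likely to be called. Regions differ in abundance and spread, and some neighbour or overlap others. An excess over independent lists therefore does not by itself show shared activity. Across regions, which are not independent replicates, log2 changes of mef2 CD2- and duf CD2- cells correlated at r = 0.475, and those of mef2 CD2+ and CD2- cells at -0.0258.

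**Figure D3:**
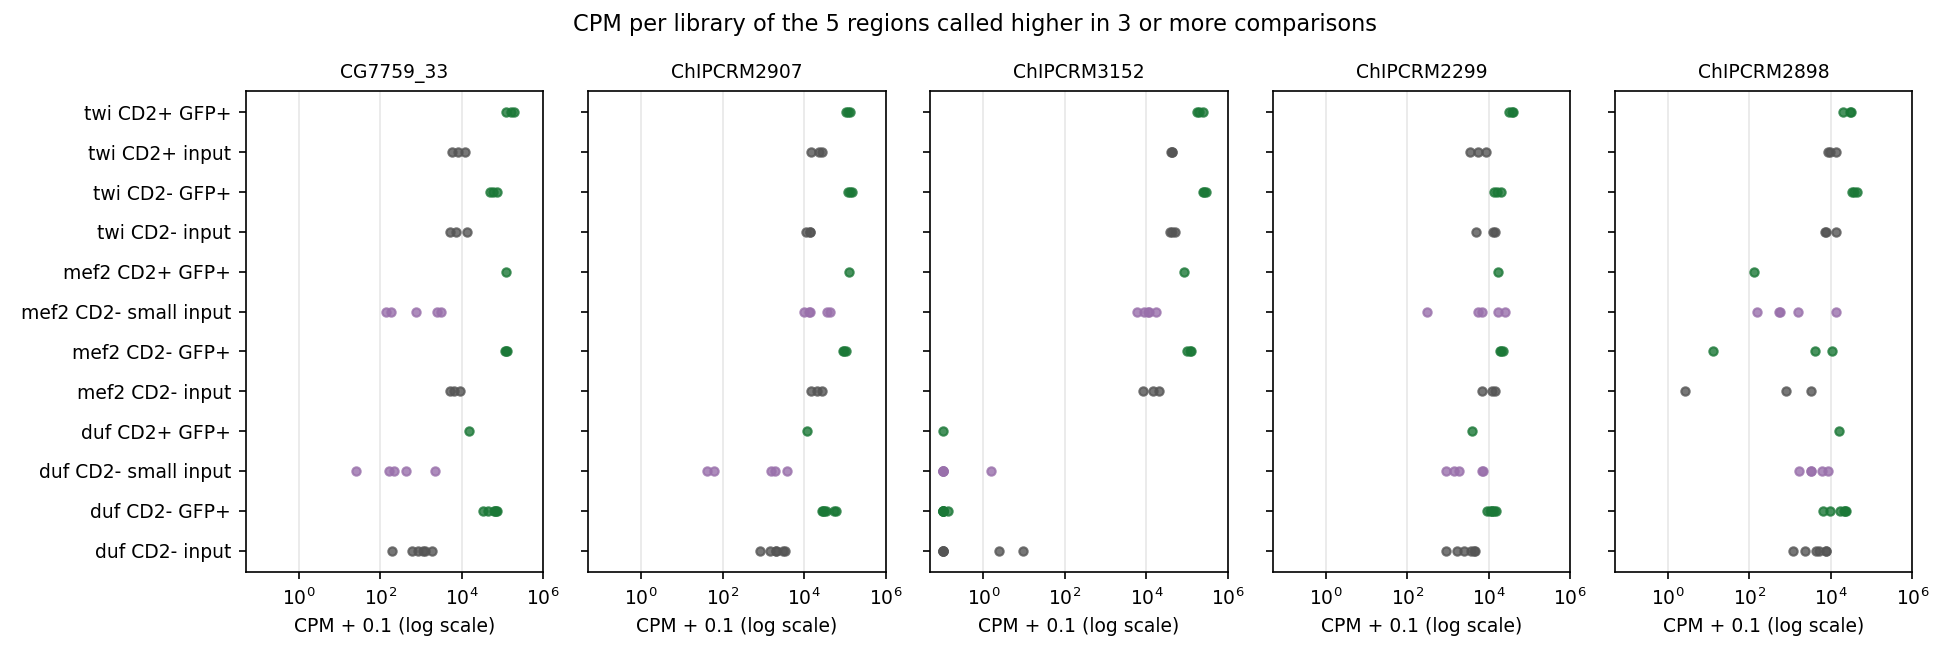
CPM plus 0.1 on a log axis in each of the 42 libraries for the 5 regions called higher in at least 3 comparisons (green GFP+, grey input, purple small input). ChIPCRM3152, at 203210 CPM in twi CD2+ GFP+ cells, is at 9.33 CPM or less in the duf libraries, inputs included. It was not tested in duf CD2- cells, so its activity there was not assessed.

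Region identifiers that carry a gene name were grouped by gene lists. Of the 62 somatic muscle and founder cell genes, 7 had regions (kon, Mef2, nau, org-1, rst, slou and sns), with 13 to 30 regions tested per comparison. In duf CD2- cells 1 of 29 rose, CG11202_down_5 (X 8338314 to 8339413), named for the T-box gene org-1, with 909 CPM against 59.98 (log2 change 5.98 ± 1.44, adjusted p 0.00843). It overlaps CG11202_down_4, so reads in the shared part may have been divided between them, and it is named after its values were seen. In the other 5 comparisons edgeR called 0 of the list, and adjusted over the list alone the counts were 1 in duf CD2- cells and 0 elsewhere. As a set the list was not found to differ from the other regions, with camera adjusted p of 0.343 to 0.754, and 0.634 to 0.767 with an estimated correlation. Of the 29 regions in duf CD2- cells, 14 were named for org-1 and 10 for slou, so the test speaks mostly to these loci. Its median log2 change was -1.20 in twi CD2+, 0.15 in twi CD2-, -4.20 in mef2 CD2+, 0.28 in mef2 CD2-, -1.05 in duf CD2+ and -0.10 in duf CD2- cells. Mean and median differ in sign in twi CD2- (mean -1.01) and duf CD2- cells (mean 0.03), and camera's direction was down in all 6, against the sign of the median in twi CD2- and mef2 CD2- cells and of the mean in mef2 CD2- and duf CD2- cells. The lists of cardiac and visceral mesoderm, epidermis and segmentation, and trachea, gut and gonad genes had 5, 3 and 1 regions, too few tested for a set test, and the blood and fat body and the nervous system and glia lists had 0.

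Some loci were covered by series of neighbouring regions, of which few were called in duf CD2- cells. At org-1, 1 of 14 tested regions was higher, at slou, a homeobox gene of muscle identity, 0 of 10, and at nej 0 of 16, with 1 lower, all by edgeR's quasi-likelihood test. These shares were not found to differ from that of the other regions (Fisher's exact p 1, 0.614 and 0.235). With so few regions per locus, even 0 calls could not be told from the share of the others. The test also takes regions as independent, although some overlap. A region without a call is not shown to be inactive.

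**Figure D4:**
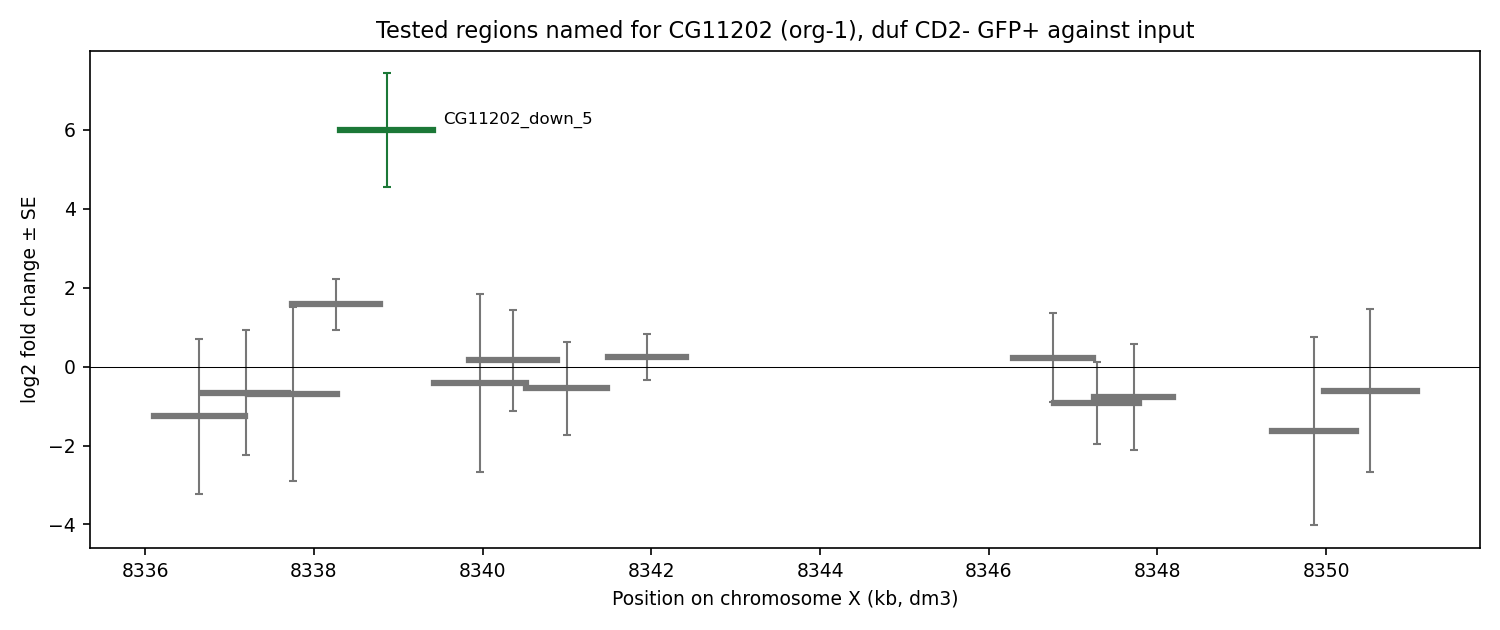
Log2 fold change with its SE (vertical bars) of the 14 tested regions named for CG11202 (org-1) in duf CD2- GFP+ cells against input, drawn at their positions on chromosome X in kb (dm3). CG11202_down_5, at 5.98, was the region called higher.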

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

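None of the tests with a prediction in this part was chosen after its result was seen, although the pattern in the small inputs was itself found in the data. The comparison of region numbers between mef2 inputs was not among the predictions. Of 64 groups of 4 to 10 values examined, 6 (9.38%) held a library far from the others, where chance alone gives about 1 in 20.

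ChIPCRM1831 (3R 4512729 to 4513672) stood out because its change against input in the single mef2 CD2+ GFP+ library differed from that in mef2 CD2- cells. The difference was -6.74 on the log2 scale in the test of the difference itself, where the median region lay at -1.45. With a single CD2+ GFP+ library, a property of that library and a difference between the cell populations are confounded.

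Single libraries stood apart from the rest of their group for 5 named regions. In duf CD2- input replicate 6, ChIPCRM5479 had 5.80 CPM against 162 to 823 in the other 5, and ChIPCRM2983 had 141 against 423 to 612. In duf CD2- input replicate 1, CBP4244 had 13.3 CPM against 213 to 539, and ChIPCRM2613 had 2665 against 6473 to 10786. In duf CD2- small input replicate 3, ChIPCRM2889 had 903 CPM against 2608 to 3444.

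In mef2 CD2- small input replicate 3, the 10 most abundant regions took 43.3% of the reads, against 35.9% to 38.0% in the other 4.

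The small duf inputs, made from 39668 cells, held 313 to 337 regions with at least 100 reads, and the 200000-cell inputs 368 to 409. Lower sequencing depth does not account for this, since after thinning all libraries to 15601850 reads the lowest 200000-cell input still exceeded the highest small input by 29 regions. The lane does not either, since both kinds of input were run in lanes 6 and 8, with gaps of 89 and 56 regions there, although the flow cell is not given in the sources used here. Fewer template molecules from fewer cells is a candidate explanation. The median SD of log2 CPM between replicates was 2.67 times as large in small as in 200000-cell duf inputs (3.10 against 1.16 over 424 regions) and 2.94 times in mef2. A larger SD in the small inputs of both drivers was the outcome predicted for this explanation beforehand, and it was met. The number of regions in mef2 inputs was not part of that prediction. The mef2 inputs do not show fewer regions, with 151 to 190 in small inputs of 20048 to 32326 cells and 157 to 172 in 200000-cell inputs. The explanation by fewer template molecules therefore stays open, as do other differences in the handling of small samples.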

How the results depend on the processing

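The alternatives that count end reads or other reads only, the duf replicates 1 to 3 or 4 to 6, the small inputs as control for duf CD2- cells and a replicate block shared by CD2+ and CD2- populations were chosen after the data were seen, and the others before. Over 942 alternatives for 56 values of named regions, 794 kept direction and side of the threshold, 145 were lost and 3 changed sign. CBP4280 and CG15319_down_8 had no value when other reads only were counted, nor ChIPCRM422 and CG15319_down_8 against the small inputs. Lost in none of 13 alternatives were CG7759_33, ChIPCRM2907 and ChIPCRM3152 in twi CD2+, twi CD2- and mef2 CD2- cells (log2 changes 2.24 or more) and ChIPCRM2078 in mef2 CD2- cells (4.24 to 7.09, adjusted p up to 0.000266). The same held for ChIPCRM2299 and ChIPCRM2497 in twi CD2+, ChIPCRM2898 in twi CD2- and CBP2861, ChIPCRM5284 and ChIPCRM5819 in mef2 CD2- cells. The most fragile were the lower regions CG15319_down_8 (lost in 16 of 21) and ChIPCRM4243 (16 of 23) in duf CD2- cells and ChIPCRM2983 (11 of 13), CBP4280 (10 of 12) and ChIPCRM2506 (10 of 13) in mef2 CD2- cells, with adjusted p up to 0.744. In that order, their log2 changes ran from -7.84 to -4.95, -3.57 to -1.15, -17.1 to -11.6, -12.0 to -8.75 and -17.7 to -14.5. ChIPCRM1831 was lost in 8 of 17 (adjusted p up to 0.0970).

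Numbers of calls moved as follows, higher then lower, and the cause was not tested unless given. With DESeq2 there were 13 and 11 in twi CD2+, 17 and 9 in twi CD2-, 1 and 1 in mef2 CD2+, 30 and 25 in mef2 CD2- and 9 and 68 in duf CD2+ cells. For differences of enrichment it gave 5 and 7 (twi), 15 and 14 (mef2) and 1 and 82 (duf), and for inputs 3 and 2, 27 and 17, and 3 and 5. On simulated counts DESeq2 called 3.48% of unchanged regions in twi CD2+ and 13.02% in duf CD2+ cells, where edgeR called 1 of 775 and 1 of 1705. In duf CD2- cells it called 2.1% of unchanged regions. Of regions changed by a log2 of 5, DESeq2 called 41% in twi CD2+ and 86% in duf CD2- cells, where edgeR called 16% and 66.5%. The simulated spread was edgeR's own estimate, so these shares do not show which of the real DESeq2 calls are false. Total-read scaling gave 6 and 4 in twi CD2+, 5 and 1 in twi CD2-, 2 and 0 in mef2 CD2+, 7 and 17 in mef2 CD2-, 0 and 0 in duf CD2+ and 22 and 95 in duf CD2- cells and 0 lower in the mef2 difference. It moves changes by the median shifts given with the methods, except in mef2 CD2+ cells, where the shift was 0.04 and the cause was not tested. Without a filter the mef2 CD2- lower count and the mef2 difference were 0 and the twi difference had 4 higher. With a mean count of at least 100, mef2 CD2+ had 2 and 2 and mef2 CD2- 3 lower. End reads only gave 2 and 3 in mef2 CD2+ cells. Other reads only gave 2 and 2 there, 3 lower in mef2 CD2-, 4 higher in duf CD2+ cells and 4 higher in the twi difference.

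With the spread from all 4 groups, mef2 CD2+ cells had 5 and 1 and duf CD2+ cells 11 higher. With all CD2- inputs as control they had 4 and 6, and 10 and 3. With the replicate number as a block, twi CD2+ had 11 and 0, twi CD2- 6 and 0, and duf CD2- cells 42 and 2. In mef2 CD2- cells same-number correlations were 0.07 to 0.19, which overlaps the range in twi cells. Whether the numbers pair libraries there is open. The block gave 7 and 0 there, with adjusted p of 0.156 for the named lower regions and ChIPCRM5556, 0.0682 for ChIPCRM2299 and 0.0749 for ChIPCRM2847. The twi difference, with either block, and the twi inputs stayed at 0 and 0. With the lane as a block duf CD2- cells had 0 and 0 from 5 libraries in place of 12, with log2 changes of the named higher regions of 4.09 to 12.04, so the loss is not evidence of a lane effect. Replicates 4 to 6 alone gave 27 higher from 6. With the small inputs as control duf CD2- cells had 25 and 1, where the spread between inputs was larger and 1 input fewer was used, and the part of cell number in this was not tested.

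Leaving out 1 library in turn gave 5 to 13 higher and 0 to 1 lower in twi CD2+, 4 to 6 and 0 in twi CD2-, 0 to 2 and 0 to 1 in mef2 CD2+, 7 to 12 and 0 to 9 in mef2 CD2-, 0 to 1 and 0 in duf CD2+ and 39 to 50 and 2 to 8 in duf CD2- cells. The twi difference had 0 to 2 and 0 to 1, the mef2 difference 0 and 0 to 2, and the others 0. Where an arm had 2 libraries left or 1, the spread was pooled. Mef2_29, not called in any alternative, changed sign 3 times. It ran from -1.47 to 0.65 in duf CD2+ cells, positive without small input replicate 3, and from -0.0774 to 2.16 in the duf difference, negative without CD2- input replicate 1. With the lane as a block it was 0.29 in duf CD2- cells.

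What depth alone limits was not tested, and the comparisons below also differ in number of libraries and in spread. In simulations edgeR found 66.5% of regions changed by a log2 of 5 and 12.5% of those changed by 2 in duf CD2- cells, but 16% and 1% in twi CD2+, 4% and 0% in twi CD2-, 5.56% and 1.11% in mef2 CD2- and 18.1% and 0.476% in duf CD2+ cells, and 0 of 120 at either size in mef2 CD2+ cells.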

Other observations

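The tests of region classes, of regions read only at their ends and of the splits that part every pair were chosen after the result was seen, and those of neighbouring regions and of the other splits were not.

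Regions of every class of identifier were called higher in duf CD2- GFP+ cells. Of 31 tested CBP regions 9 (29.03%) were higher, against 38 of 369 others (10.3%), with CBP4242 the strongest at a log2 change of 7.97. Of 82 regions named for a gene 3 (3.66%) were higher, against 44 of 318 others (13.8%), and 32 of 240 ChIPCRM, 2 of 39 DHS_FC and 1 of 8 DHS_FCM regions were. That CBP regions may be active more often, and regions named for a gene less often, was tested with Fisher's exact test, 2-sided. The p-values were 0.00541 and 0.0111, and 0.162 and 0.167 when adjusted over 30 class tests, so neither hypothesis passed.

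Some neighbouring regions were called together in duf CD2- cells. CBP4242 and CBP4244, 2272 bp apart, rose by 7.97 and 5.87 on the log2 scale, CBP2861 and CBP2862, 977 bp apart, by 4.15 and 4.58, and ChIPCRM2299 and ChIPCRM2300, 1842 bp apart, by 4.09 and 5.94. Of the 47 regions called higher, 18 had another within 25 kb, against a mean of 11.3 in 10000 random draws (permutation p 0.0509, adjusted over 7 tests 0.125), so the pattern itself did not pass. Draws matched on GC content gave a p of 0.0292 (adjusted 0.125), draws matched on input CPM 0.0536 (0.125) and pairs that do not overlap 0.0966 (0.137). The bound of 0.05 set for these tests made no allowance for their number, and after adjustment GC content, input abundance and divided reads all stay open. The pattern was not clear in twi CD2+ cells (2 of 10, p 0.256), twi CD2- cells (2 of 6, p 0.0977) or mef2 CD2- cells (0 of 10), and random calls passed in 5 of 200 simulations (2.5%). A shared regulatory element is 1 biological reading that was not tested.

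In twi and mef2 inputs, 14 regions had reads at their ends and almost none inside in at least 5 of the 9 inputs. The most abundant was CG15319_down_9, named for nej, with 1769687 end reads and 0 others, a mean of 9977 CPM. Inner positions where no read can be placed do not account for most of the 14. A share of 0.786 (11 of 14) had at least 1000 other reads in some library, 8 of these in duf libraries alone. The cut-off of 1000 takes no account of end reads, however. CG15319_down_9 passed it with at most 2494 other reads, in duf CD2- input replicate 6, while it averaged 13061 CPM in duf inputs. That library held 25534591 reads in all regions. For CG15319_down_9 this explanation stays open, as it does for the other 3 of the 14, which had 3 or fewer other reads. Reads from 1 end only do not account for most of the 14 either, since the median share of the better covered end was 0.606. CBP5470, ChIPCRM5283 and DHS_FC_20 were read almost only at 1 end. A short product that lacks the inner part could leave such reads and was not tested, and no biological explanation was tested.

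Other splits of the same libraries were set against the number of calls. The replicate numbers were taken to pair GFP+ and input libraries in duf CD2- cells. Of the 32 splits that part every pair, 1, the real one, gave as many as its 52 calls, while the highest other gave 1. Of 100 splits drawn without regard to the pairs, 1, the real one, did so, and the highest other gave 2. Both shares are under 0.05 and the smallest that these numbers of splits can give. They concern only the grouping of these libraries, which may be technical replicates. Splits that mix GFP+ and input libraries also widen the spread within groups, so chance is not excluded. For twi CD2+, twi CD2- and mef2 CD2- cells the 10 possible splits are too few to give a share under 0.05. The real split, 1 of 10 in each, gave 10, 6 and 17 calls, and the highest other 1, 0 and 0. The 4 splits that part every twi pair are too few as well, with 0 calls in the highest other in both twi CD2+ and twi CD2- cells. Where the real count was 0, every split reaches it, so the counts of 100 of 100 splits for the twi difference of enrichment and of 10 of 10, 56 of 56 and 100 of 100 for the twi, mef2 and duf inputs decide nothing. The highest other gave 8, 0, 1 and 1 calls.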
